A study of Homo sapiens with 18 samples.

How the data were processed

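RNA was measured in 18 libraries from 3 established liver cancer lines, Huh7, SNU-387 and SNU-475, each with 3 libraries labelled b-catenin and 3 labelled vector. The deposited table holds expected counts, estimated numbers of reads per gene symbol that need not be whole, in 1 column per library, and per the submitters' processing notes the tools were RSEM 1.2.15 and Bowtie2 2.1.0 with the genome build hg38, without their order or role. Per the labels' protocols, RNA was extracted with Trizol and purified on columns, and per the series text it was poly(A)-selected and sequenced on an Illumina instrument. Gene annotation, read layout, strand and filters are not stated, and reads were not analysed here. The table has 26475 symbols, of which 3306 had no count in any library, and its columns were matched to the labels with 0 left unmatched. Between 9.43% and 15.2% of the values of a library were not whole numbers. It has 4 ribosomal RNA genes, which held between 1.996% and 21.97% of the counts of a library, and 0 mitochondrial genes.

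Total counts per library lay between 40595763 and 63340459, so that 1 CPM stands for 40.6 counts or more in each library. Ratios for genes with 1 to 3 counts in a group are given with a 95% counting interval, and a group with no counts was set to a floor of 3 counts over the group. These intervals and floors cover counting error only. PCR copies were not separated from independent molecules.

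Expected counts were rounded to whole numbers. Genes with low counts were removed with edgeR's filterByExpr (minimum count 10), libraries were scaled with TMM factors, and groups were compared with edgeR's quasi-likelihood test with robust estimation and Benjamini-Hochberg adjustment at 0.05 (R 4.3.3, edgeR 4.0.16, limma 3.58.1). Within each line, b-catenin was compared with vector in a fit of its own 6 libraries. The average over the lines, the differences of the change between lines (an interaction) and the comparisons of vector libraries between lines came from 1 fit of all 18 libraries with 6 group means. SE of log2 fold changes came from the test's F value and 95% intervals from the t distribution with the test's degrees of freedom, with a prior count of 2 for log2 CPM. Overlaps of calls between lines, which share no control libraries, were tested with Fisher's exact test, two-sided, per direction, against the number expected from independent lists. Single comparisons of CTNNB1 were also tested with a two-sided exact permutation test, for which 3 against 3 gives at least 0.1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

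The groups, the tests, the gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. The 30 lists were Wnt feedback and core target genes, other reported beta-catenin target genes, perivenous hepatocyte, periportal hepatocyte, secreted liver protein, liver transcription factor, hepatoblast and progenitor, mesenchymal, epithelial, cell cycle, interferon response, antigen presentation, chemokine and cytokine, TGF-beta response, YAP target, cholesterol synthesis, fatty acid synthesis, hypoxia and glycolysis, unfolded protein response, ATF4 stress, NRF2 target, p53 target, cadherin-catenin adhesion, beta-catenin destruction and transcription complex, ribosomal protein and replication-dependent histone genes, and markers of endothelial cells, blood cells, hepatic stellate cells and fibroblasts, and bile duct cells. They were written from general knowledge. Of the marker lists, 0 of 15 endothelial, 0 of 16 blood cell, 5 of 19 stellate cell and 5 of 15 bile duct genes are in another list, and in the order Huh7, SNU-387, SNU-475 the vector libraries had 3, 5 and 9, 5, 5 and 3, 10, 14 and 17, and 12, 8 and 10 of them at 1 CPM or more. Lists were tested with limma's camera with a preset correlation of 0.01 on log2 CPM, adjusted over the lists and the 4 comparisons (each line and the average), again with an estimated correlation, and with fry. The same test was run for the differences between lines and for the vector libraries, adjusted within those families.

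For each line the text names CTNNB1 first, then the 10 genes with the largest change in each direction among those with an adjusted p under 0.05, a mean of at least 5 CPM in the higher group and no overlap between the groups, and up to 4 members of each list with the smallest p. For the average and the differences it names 8 genes per direction, for vector libraries 5, and for genes called in each line up to 8 per direction. Of the 16 genes of each difference only those with more than 3 counts in each of the 4 groups are named. Clone and locus names and genes that vary with sex were left out. Genes named after their values were seen are marked as such. Some genes that the rule would name are not reported.

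The steps were tested on simulated counts drawn from the real means and library sizes with 200 genes changed. In Huh7 1.49% of the genes changed 1.5-fold were recovered, 4.48% at 2-fold and 66.7% at 4-fold, with 5 false calls among 15406 genes. In SNU-387 the shares were 62.7%, 77.6% and 92.4% with 10 false calls among 15627 genes, in SNU-475 50.7%, 80.6% and 92.4% with 14 among 16220, and for SNU-387 minus Huh7 2.99%, 37.3% and 89.4% with 5 among 18055. With nothing changed SNU-475 minus Huh7 gave 0 calls among 18055 genes. A first version with the smaller folds alone recovered 0 genes in Huh7, and the 4-fold change was added after that was seen. In Huh7 the fitted sizes had medians of 0.58, 1.00 and 1.97 on the log2 scale. With 1 raised list in simulated SNU-475 counts of 16236 genes, camera called that list and 0 others. Power in Huh7 was therefore low for small changes of few genes.

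Alternatives to these choices were no low-count filter, a filter at 5 CPM in 3 libraries, RLE size factors, library size only, DESeq2 1.42.0, limma-voom, the replicate number as a block, all 18 libraries in 1 fit for single lines, the 9 vector libraries only for vector comparisons, a fold change of at least 1.5, camera with an estimated correlation, fry, and leaving out each replicate in turn. Leaving out Huh7 b-catenin replicate 1 and vector replicate 3 together, and removing the 4 ribosomal RNA genes, were added after the data were seen. Positions, transcript lengths and GC content came from the GENCODE annotation of GRCh38, the assembly that hg38 names. Length and GC content are those of the longest transcript of a gene. Older and newer symbols were linked through the synonyms of a RefSeq table, and 24652 of the 26475 symbols (93.1%) were placed. Running medians were taken over 31 neighbouring genes with a mean of at least 2 CPM and compared with 200 shuffled gene orders, at a size beyond 0.7 chosen after a first look at the data. Trends on GC content and length were removed with loess (span 0.5).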

Results

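RNA was sequenced from 3 human liver cancer cell lines, Huh7, SNU-387 and SNU-475, in 18 libraries. Each line had 3 libraries labelled b-catenin and 3 labelled vector, the control. The series text calls them biological replicates of poly(A)-selected RNA. Huh7 is a hepatocellular carcinoma line that makes many liver proteins, and SNU-387 and SNU-475 are hepatocellular carcinoma lines with few of them. Huh7 was grown in DMEM and the SNU lines in RPMI, so line and medium cannot be told apart. The labels do not say how b-catenin was expressed. In replicate order the total counts were 54236902, 43723803 and 47836884 in the Huh7 libraries labelled b-catenin and 47043765, 53193082 and 44488356 in Huh7 vector. They were 54744610, 46580548 and 53752182 in SNU-387 b-catenin and 40595763, 54337370 and 52829040 in SNU-387 vector. In SNU-475 they were 45769738, 43058980 and 48080533 with the b-catenin label and 42946327, 47616548 and 63340459 in vector. The first principal component held 47.1% of the variance and the next 29.3%, and both separated the lines. Replicates of Huh7 were less alike than those of the other lines: the biological coefficient of variation was 27.3% in Huh7, 9.44% in SNU-387 and 11.7% in SNU-475. Huh7 b-catenin replicate 1 correlated across genes at 0.933 and 0.946 with the other libraries of its group, which correlated at 0.990 with each other. Ribosomal RNA genes held 21.97% of its counts against 5.38% and 1.996% in those. Levels are given as CPM, counts scaled to a common library total, as mean ± SD over 3 libraries (n = 3), and log2 fold changes are b-catenin against vector unless other groups are named. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

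CTNNB1 encodes beta-catenin, a protein of cell junctions and the transcriptional effector of Wnt signalling, and was examined first because the labels name its product. It lies on chromosome 3 from 41194741 to 41260096 of GRCh38. In SNU-387 it was higher in the libraries labelled b-catenin, 325 ± 32.2 against 218 ± 19.4 CPM, a log2 fold change of 0.57 ± 0.085 (SE, edgeR adjusted p = 7.73e-06). In Huh7 no difference was detected, with 669 ± 251 against 675 ± 88.0 CPM, a log2 fold change of -0.01 (95% interval -0.73 to 0.70) and an edgeR adjusted p of 0.976. Huh7 b-catenin replicate 1 had 385.5 CPM and the others of that group 863 and 757 CPM. In SNU-475 the levels were 212 ± 24.4 against 184 ± 10.3 CPM, a log2 fold change of 0.20 (95% interval -0.02 to 0.42) that did not pass the test (edgeR adjusted p = 0.0973). Without SNU-475 b-catenin replicate 2 the log2 fold change was 0.29 with an edgeR adjusted p of 0.00394, within a range of 0.00394 to 0.605 over its 15 alternatives. Over the alternatives with every library kept it lay between -0.13 and 0.22, so its sign depends on the processing. The two-sided exact permutation p was 1 in Huh7, 0.1 in SNU-387 and 0.2 in SNU-475, and 3 against 3 cannot go below 0.1. In SNU-387 other genes of chromosome 3 rose too, with a median of 0.38 over 695 genes (411 called higher and 128 lower) and 0.19 over the 31 neighbouring genes around CTNNB1. Its rise there is therefore no clear check of the label, and the groups are called "labelled b-catenin" throughout. The changes did not differ detectably between lines by the interaction test (SNU-387 minus Huh7 0.65, adjusted p = 0.0835; SNU-475 minus Huh7 0.22, adjusted p = 0.573; SNU-475 minus SNU-387 -0.43, adjusted p = 0.259). Each difference had an SE of 0.3, because the fit of all 18 libraries shares the spread of a gene over the lines. SNU-475 minus SNU-387, which holds no Huh7 library, thus carried the wider spread of Huh7. The fits of single lines had SEs of 0.085 in SNU-387 and 0.096 in SNU-475. Single Huh7 libraries decided 2 of these calls. Without Huh7 b-catenin replicate 2 SNU-387 minus Huh7 was 0.82 (edgeR adjusted p = 0.0284, range over 27 alternatives 0.0103 to 0.224). Without Huh7 b-catenin replicate 1 SNU-475 minus SNU-387 stayed at -0.43 (edgeR adjusted p = 0.0325, range 0.00866 to 0.473), so the spread and not the estimate changed that call. Counts are per gene, so transcripts of the chromosomal gene and of an introduced copy were not separated.

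**Figure D1:**
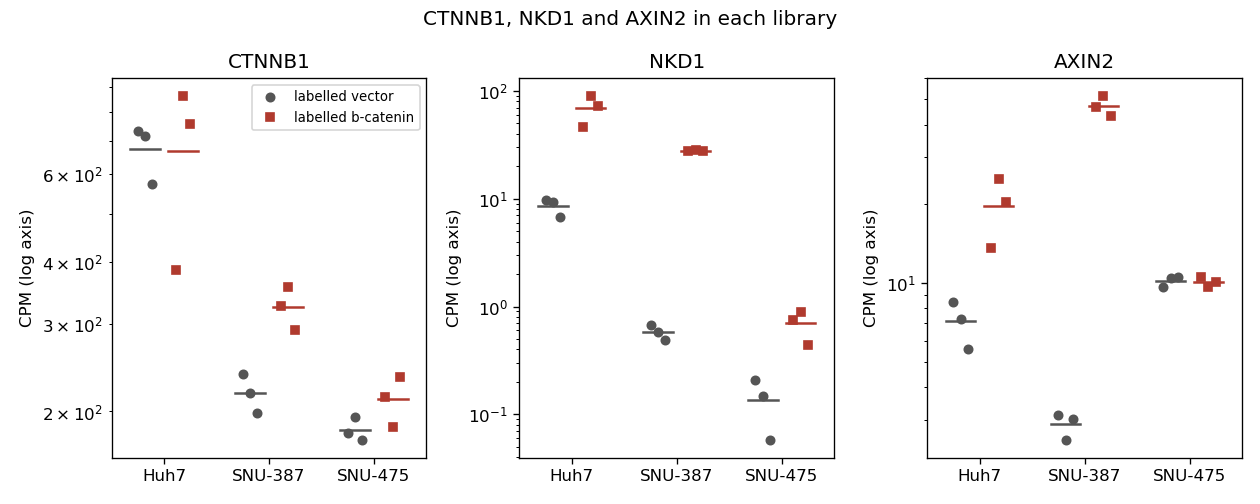
CPM (log axis) of CTNNB1, NKD1 and AXIN2 in each of the 18 libraries, with points for libraries and a line for each group mean. NKD1 means were 69.9 against 8.64 CPM in Huh7, 27.8 against 0.583 in SNU-387 and 0.696 against 0.137 in SNU-475, and AXIN2 was higher in Huh7 and SNU-387 but not in SNU-475.

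In Huh7 the Wnt pathway's own feedback genes were higher in the libraries labelled b-catenin. The secreted Wnt antagonist DKK1 had 1194 ± 133 against 231 ± 32.0 CPM (log2 fold change 2.37, edgeR adjusted p = 0.000127). NKD1, an inhibitor of Dishevelled, rose by 3.02 on the log2 scale. TCF7, a DNA-binding partner of beta-catenin, rose from 9.07 ± 0.872 to 32.1 ± 1.78 CPM. The Wnt receptor gene FZD7 fell from 29.8 ± 0.887 to 9.71 ± 0.539 CPM. Of 2 genes named after their values were seen, the scaffold gene AXIN2 had 19.6 ± 5.67 against 7.12 ± 1.44 CPM (1.46, edgeR adjusted p = 0.00496). The other, the stem cell receptor gene LGR5, had 50.7 ± 15.7 against 12.2 ± 2.1 CPM (2.06, edgeR adjusted p = 0.00138). Of 21 tested Wnt feedback and core target genes 14 were higher and 3 lower (15 and 3 adjusted over the list alone), with a median of 1.32 (camera adjusted p = 0.00161; adjusted p = 0.322 with an estimated correlation). AMER1, an X-linked scaffold of the beta-catenin destruction complex, was near the detection limit in the vector libraries and had 13.7 ± 4.39 against 0.144 ± 0.0536 CPM (log2 fold change 6.54, edgeR adjusted p = 6.91e-05).

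Epithelial genes were higher in Huh7, and single fetal liver genes went both ways. The membrane protease gene ST14 had 141 ± 8.05 against 1.38 ± 0.211 CPM, the splicing regulator ESRP1 119 ± 22.6 against 0.900 ± 0.0432 CPM, and SPINT1, which encodes an inhibitor of ST14's product, 316.5 ± 13.0 against 40.8 ± 4.46 CPM. Among 22 tested epithelial genes 16 were higher and 3 lower (17 and 3 adjusted over the list alone), with a median of 1.32 (camera adjusted p = 0.000115; adjusted p = 0.177 with an estimated correlation). The cadherin-catenin adhesion list had 9 higher and 0 lower of 18 (10 and 0 adjusted over the list alone), a median of 0.98 and JUP, CDH6 and CDH1 among its members (camera adjusted p = 0.00483; adjusted p = 0.612 with an estimated correlation). CDH1, the epithelial cadherin whose tail binds beta-catenin, rose from 35.8 ± 7.20 to 149 ± 29.1 CPM. The imprinted fetal transcript H19 rose from 56.6 ± 5.74 to 8825 ± 1359 CPM (log2 fold change 7.28, edgeR adjusted p = 1.09e-05). Its neighbour IGF2, a fetal growth factor, rose from 1974 ± 69.9 to 9719 ± 532 CPM. The surface marker EPCAM rose to 464 ± 92.3 from 47.5 ± 4.25 CPM. The fetal serum protein gene AFP fell from 4125 ± 219 to 149.5 ± 19.5 CPM (-4.79, edgeR adjusted p = 2.11e-05). Mesenchymal genes were lower, 13 of 21 with 4 higher and a median of -1.72 (camera adjusted p = 0.00812; adjusted p = 0.472 with an estimated correlation). Of these the matrix genes COL6A1 and SPARC fell by 2.86 and 2.49 on the log2 scale.

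Interferon, hypoxia and sterol genes were lower in the Huh7 libraries labelled b-catenin, and amino acid stress genes were higher. Of 28 interferon response genes 15 were lower and 1 higher (17 and 1 adjusted over the list alone), with a median of -1.54 (camera adjusted p = 7.71e-06; adjusted p = 0.0902 with an estimated correlation). The antiviral GTPase genes MX1 and MX2 fell by 2.75 and 3.03 on the log2 scale. The transcription factor gene IRF7 was the member that rose, from 0.0779 ± 0.0306 to 3.44 ± 0.493 CPM. Of 25 hypoxia and glycolysis genes 19 were lower and 0 higher (20 and 1 adjusted over the list alone), with a median of -0.95 (camera adjusted p = 5.19e-06; adjusted p = 0.0902 with an estimated correlation). The glycolytic enzyme genes ALDOC and ENO2 fell by 3.37 and 2.22 on the log2 scale. Cholesterol synthesis genes had 8 lower and 0 higher of 21 and a median of -0.32 (camera adjusted p = 0.0155; adjusted p = 0.28 with an estimated correlation), with INSIG1, a sterol sensor, at 55.8 ± 3.65 against 275 ± 8.99 CPM. Of 23 ATF4 stress genes 15 were higher and 0 lower (15 and 1 adjusted over the list alone), with a median of 1.12 (camera adjusted p = 4.04e-05; adjusted p = 0.177 with an estimated correlation). CHAC1, which degrades glutathione, had 71.7 ± 2.26 against 4.65 ± 0.854 CPM. The folate enzyme gene MTHFD2 and the asparagine synthetase gene ASNS rose by 1.75 and 1.73 on the log2 scale. The 6 tested endothelial markers, led by FLT1 and LYVE1, included 5 lower genes, all under 5 CPM, with a median of -1.86 (camera adjusted p = 0.00635; adjusted p = 0.177 with an estimated correlation; 0.0614 without b-catenin replicate 1 and vector replicate 3, range over 9 alternatives 0.00174 to 0.0614).

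Among the top genes of the fixed rule in Huh7 were several with no or almost no counts in the vector libraries. PLXDC2 was at least 364-fold, PHKA1 at least 363-fold and L3MBTL4 at least 365-fold higher, computed against a floor of 3 counts over a group at 0. With 1 to 3 vector counts the ratios were 966 (95% counting interval 267 to 7980) for the phosphatase gene PTPRD, 1110 (199 to 43900) for the neural factor POU4F1, 761 (260 to 3690) for the antimicrobial peptide gene DEFB1. They were 404 (138 to 1960) for ZXDB and 352 (120 to 1710) for the nucleosome-binding gene HMGN5. Intervals and floors cover counting error only. The motor protein gene MYO10 had 189.9 ± 20.5 against 0.199 ± 0.0899 CPM (edgeR adjusted p = 1.09e-05), and the glycophorin gene GYPC had 20.9 ± 6.88 against 0.0478 ± 0.0828 CPM. PHKA1, ZXDB and HMGN5 are on the X chromosome, as is AMER1, where the running median over 31 neighbouring genes peaked at 2.52 at ZC4H2. The largest falls were in C1orf95 (ratio 1360, interval 243 to 53600), the calprotectin subunit gene S100A9, the receptor gene SORCS2 and HAMP, the iron hormone hepcidin, which had 0.837 ± 0.507 against 151 ± 56.4 CPM. The adhesion gene TENM2, the laminin gene LAMA4, the lipoxygenase gene ALOX15B, the serum protein gene ITIH3 and the homeobox gene PRRX2 fell as well. The urea cycle gene ARG1 fell from 67.7 ± 6.51 to 1.13 ± 0.313 CPM.

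By edgeR 6875 of 15646 tested genes (43.9%) changed in Huh7, 3473 higher and 3402 lower, of which 6376 changed at least 1.5-fold. Leaving out b-catenin replicate 1 and vector replicate 3, the libraries farthest from their groups, 11683 were called. Leaving out libraries chosen for their distance lowers the spread within groups, so a rise in calls is in part built into that choice. Of the 30 lists 16 had the same counts of called genes adjusted over the list alone, and no other list changed by more than 3 genes per direction. Neighbouring genes changed together, with a median of -0.49 on chromosome 9 (42 called higher and 197 lower) and 0.48 on chromosome 21.

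In SNU-387 the libraries labelled b-catenin carried more RNA of the Wnt targets LGR5, NKD1 and AXIN2 and less of the matrix genes POSTN and COL1A2. LGR5 had 12.01 ± 0.994 against 0.0431 ± 0.0386 CPM (log2 fold change 8.12, edgeR adjusted p = 1.23e-14), NKD1 27.8 ± 0.409 against 0.583 ± 0.0889 CPM (5.59, edgeR adjusted p = 5.47e-17) and AXIN2 47.3 ± 4.17 against 2.88 ± 0.334 CPM (4.04, edgeR adjusted p = 4.66e-16). The growth regulator MYC, on chromosome 8 where most genes were higher, had 176 ± 1.56 against 43.6 ± 1.6 CPM. Wnt feedback and core targets as a list were mixed, with 11 higher and 8 lower of 21 and a median of 0.47, and the list was not called (camera adjusted p = 0.385). CD24, a surface marker of progenitor cells, rose from 14.4 ± 1.30 to 764 ± 23.2 CPM. Periostin (POSTN) fell from 795 ± 86.3 to 1.16 ± 0.0350 CPM (-9.43, edgeR adjusted p = 7.54e-20), and the collagen gene COL1A2 from 6025 ± 1143 to 87.2 ± 4.37 CPM. The collagen cross-linking gene LOX fell by 2.59 and the protease gene MMP2 by 1.99 on the log2 scale. Of 26 mesenchymal genes 19 were lower and 3 higher, with a median of -1.19 (camera adjusted p = 0.000438; adjusted p = 0.161 with an estimated correlation).

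Cell cycle genes were higher in the same libraries. Of 32 cell cycle genes 28 were higher and 0 lower, with a median of 0.79 (camera adjusted p = 4.84e-08; adjusted p = 0.103 with an estimated correlation). The replication helicase genes MCM4 (269 ± 2.41 against 72.5 ± 1.46 CPM) and MCM2 (235 ± 5.37 against 65.1 ± 4.55 CPM) led them with the cyclin gene CCNA2. MCM4 is on chromosome 8. ATF4 stress genes had 17 higher and 4 lower of 22 and a median of 0.54 (camera adjusted p = 0.00206; adjusted p = 0.163 with an estimated correlation). CTH, which makes cysteine, had 257 ± 3.99 against 14.6 ± 0.472 CPM. NRF2 targets had 15 higher and 2 lower of 20 and a median of 0.59 (camera adjusted p = 0.000858; adjusted p = 0.256 with an estimated correlation). The glutathione synthesis gene GCLC had 159 ± 9.62 against 31.8 ± 2.42 CPM, and the oxidative stress gene OSGIN1 was also higher. Hypoxia and glycolysis genes had 20 higher and 5 lower of 26 (20 and 6 adjusted over the list alone) and a median of 0.68 (camera adjusted p = 0.00482; adjusted p = 0.232 with an estimated correlation). Of these the oxygen sensor EGLN3 and the mitophagy gene BNIP3 rose by 1.97 and 1.49 on the log2 scale. The carbonic anhydrase gene CA9 fell by 2.96 and the collagen hydroxylase gene P4HA2 by 1.6.

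Interferon response and chemokine genes were lower in the SNU-387 libraries labelled b-catenin. Of 30 interferon response genes 26 were lower and 2 higher (27 and 3 adjusted over the list alone), with a median of -1.98 (camera adjusted p = 2.1e-07; adjusted p = 0.0902 with an estimated correlation). IFI27 had 1.32 ± 0.114 against 65.5 ± 7.02 CPM, and the RNA sensor gene OAS2 and IFI44L fell by 2.70 and 3.36 on the log2 scale. Chemokine and cytokine genes had 18 lower and 5 higher of 24 and a median of -0.79 (camera adjusted p = 0.0111; adjusted p = 0.322 with an estimated correlation). The growth factor CSF2 had 1.57 ± 0.335 against 45 ± 1.82 CPM, and IL1B was lower by the same test. Antigen presentation genes had 12 lower and 2 higher of 17, and the list was not called (camera adjusted p = 0.0602). The monocyte attractant genes CCL7 (ratio 3560, interval 638 to 141000) and CCL8 were among the largest falls. Of 9 endothelial markers 7 were lower and 1 higher, with a median of -2.87 and the receptor genes TEK and ROBO4 at 5.40 ± 0.506 and 4.28 ± 0.443 CPM in the vector libraries (camera adjusted p = 0.0112; adjusted p = 0.189 with an estimated correlation).

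Other top genes in SNU-387 were the skin barrier gene FLG (28.9 ± 2.61 against 0.0896 ± 0.0489 CPM, edgeR adjusted p = 6.02e-17), the ubiquitin-conjugating UBE2QL1 (10.97 ± 1.09 against 0.0268 ± 0.00896 CPM), and HPGD, which inactivates prostaglandins (40.9 ± 1.93 against 0.352 ± 0.0125 CPM). FAM151A, KHDC1L, the phosphatase gene DUSP2, BPIFA2 and the cancer-testis antigen genes MAGEC1 and MAGEC2 rose too, MAGEC2 to 50.4 ± 0.361 from 0.369 ± 0.0929 CPM. FAR2P1, a pseudogene whose reads may be shared with its relatives, had 0 counts in the libraries labelled b-catenin and was at least 322-fold lower. RANBP3L (ratio 1260, interval 226 to 50000) and the homeobox gene PKNOX2 (392, 108 to 3240) had almost no counts there, and the phosphatase gene PTPRO, lactoferrin (LTF), the trypsinogen PRSS2 and the guidance gene SEMA3E fell by 8.74 to 10.26 on the log2 scale. By edgeR 11285 of 15836 tested genes (71.3%) changed, 5464 higher and 5821 lower, and 7219 of them by at least 1.5-fold. On chromosome 8 the median log2 fold change was 1.01, with 357 of 418 genes called higher and 36 lower, and ribosomal protein genes there (RPL30, RPL8) rose with it. Chromosome 4 had a median of 0.62 and chromosome 13 one of -0.41. Of the 30 lists 26 had the same counts adjusted over the list alone, and the others changed by at most 1 gene per direction.

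In SNU-475 the libraries labelled b-catenin carried more RNA of interferon response and chemokine genes. Of 34 interferon response genes 34 were higher, with a median of 4.83 (camera adjusted p = 4.17e-23), and the call held with an estimated correlation (adjusted p = 0.0151). The antiviral genes MX1 (1071 ± 23.3 against 13.3 ± 0.142 CPM, log2 fold change 6.33, edgeR adjusted p = 3.63e-09), RSAD2 (65.9 ± 5.27 against 0.0638 ± 0.0240 CPM), OASL (577 ± 50.1 against 0.589 ± 0.163 CPM) and IFIT1 (669.9 ± 21.2 against 16.4 ± 0.262 CPM) rose. So did CMPK2, IFI44, OAS2 and the nucleic acid sensor ZBP1 (ratio 1320, interval 237 to 52300). Of 23 chemokine and cytokine genes 20 were higher and 0 lower, with a median of 1.90 (camera adjusted p = 6.14e-08; adjusted p = 0.111 with an estimated correlation). The inflammatory cytokine gene IL6 had 206 ± 26.0 against 7.65 ± 0.292 CPM, and the T cell attractant genes CXCL10 and CXCL11 had 119 ± 17.2 and 19.2 ± 0.433 CPM against 1.26 ± 0.277 and 0.102 ± 0.0279 CPM. CCL3 rose as well, although its near copies make its count uncertain. Antigen presentation genes had 13 higher and 3 lower of 17 and a median of 0.60 (camera adjusted p = 0.0134; adjusted p = 0.488 with an estimated correlation). The peptide transporter gene TAP1 had 416 ± 16.6 against 92.5 ± 1.47 CPM. The class II genes HLA-DRA and CD74 were lower by 3.02 and 3.38 on the log2 scale.

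Unfolded protein response genes were higher in SNU-475. HSPA5, the main chaperone of the reticulum, had 14900 ± 1662 against 1906 ± 49.3 CPM (log2 fold change 2.97, edgeR adjusted p = 1.55e-07), the disulphide isomerase gene PDIA4 4675 ± 123 against 611 ± 14.01 CPM, and HERPUD1, which clears misfolded proteins, 647 ± 26.2 against 66.1 ± 1.89 CPM. Of 19 unfolded protein response genes 18 were higher and 0 lower (19 and 0 adjusted over the list alone), with a median of 1.96 (camera adjusted p = 1.92e-10; adjusted p = 0.061 with an estimated correlation). The heat shock gene HSPA6 had 1621 ± 81.7 against 9.34 ± 0.890 CPM, and its near-identical relative HSPA7, whose counts cannot be separated with certainty, moved with it. Of 23 ATF4 stress genes 22 were higher and 0 lower, with a median of 1.73 (camera adjusted p = 2.48e-11; adjusted p = 0.161 with an estimated correlation). PPP1R15A, which restarts translation after stress, had 981 ± 21.6 against 74.4 ± 2.1 CPM, and STC2 and ATF3 rose by 2.6 and 2.82 on the log2 scale. Hypoxia and glycolysis genes had 20 higher and 3 lower of 26 and a median of 0.82 (camera adjusted p = 3.88e-05; adjusted p = 0.0902 with an estimated correlation), led by CA9, NDRG1 and the vessel growth factor gene VEGFA, which had 211 ± 19.1 against 49.2 ± 1.72 CPM. YAP targets had 13 higher and 4 lower of 22 and a median of 0.56 (camera adjusted p = 0.0187; adjusted p = 0.542 with an estimated correlation), with NT5E and NUAK2 higher and CTGF lower by 2.1 on the log2 scale.

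Cholesterol synthesis, fatty acid synthesis and cell cycle genes were lower in the same libraries. Of 21 cholesterol synthesis genes 19 were lower and 1 higher (19 and 2 adjusted over the list alone), with a median of -1.52 (camera adjusted p = 4.94e-09), and the call held with an estimated correlation (adjusted p = 0.0446). INSIG1 had 13.2 ± 0.350 against 106 ± 5.47 CPM, the farnesyl diphosphate synthase gene FDPS 70.0 ± 7.38 against 413 ± 16.8 CPM, and the squalene epoxidase gene SQLE 58.0 ± 1.62 against 209.8 ± 6.27 CPM. Fatty acid synthesis genes had 11 lower and 2 higher of 15 (12 and 2 adjusted over the list alone) and a median of -0.71, with the desaturase genes FADS2 and SCD among them (camera adjusted p = 0.00256; adjusted p = 0.414 with an estimated correlation). Cell cycle genes had 22 lower and 2 higher of 32 (24 and 2 adjusted over the list alone) and a median of -0.41 (camera adjusted p = 0.00037; adjusted p = 0.0902 with an estimated correlation). The kinesin gene CENPE had 17.5 ± 2.33 against 45.6 ± 0.861 CPM, MCM5 was lower and the licensing gene CDC6 higher. Replication-dependent histone genes, a family of near copies, had 10 lower and 0 higher of 15 (12 and 0 adjusted over the list alone). Their median was -1.22, with HIST1H1C and HIST2H2BE among them (camera adjusted p = 0.00199, and 0.247 with an estimated correlation). Only 9 of the 17 members reached 1 CPM in the SNU-475 vector libraries. Whether the poly(A) selection of the RNA affected these counts was not tested. NRF2 targets had 12 lower and 3 higher of 20 and a median of -0.39 (camera adjusted p = 0.0345; adjusted p = 0.289 with an estimated correlation; 0.0533 without b-catenin replicate 1, range over 8 alternatives 0.0283 to 0.0588). The aldo-keto reductase AKR1B10 had 843 ± 71.2 against 3266 ± 63.8 CPM, and AKR1C2, a member of a family of near copies, fell too.

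Wnt genes went both ways in SNU-475. AXIN2, named here after its values were seen, had 10.1 ± 0.470 against 10.2 ± 0.470 CPM (log2 fold change -0.02, edgeR adjusted p = 0.896; -0.34 with an adjusted p of 0.0104 with library size only, range over 15 alternatives 0.0104 to 0.996). NKD1 rose by 2.38 on the log2 scale (edgeR adjusted p = 0.00352) while below 1 CPM in every library. APCDD1, a Wnt inhibitor of the cell surface, fell from 35.9 ± 0.553 to 1.78 ± 0.435 CPM, FZD7 fell by 1.70 on the log2 scale and the Wnt antagonist SFRP2 from 28.03 ± 2.04 to 1.96 ± 0.579 CPM. RNF43, which removes Wnt receptors, and MYC rose by 1.89 and 1.02 on the log2 scale. The Wnt feedback and core target list had 8 higher and 6 lower of 20 and a median of 0.16, or -0.17 with library size only (camera adjusted p = 0.643). Other large falls were in the peptide hormone gene EDN3, the endothelial glycoprotein EMCN, S100A8, the protease inhibitor A2M (15.03 ± 1.31 against 255 ± 9.59 CPM), LAMP5, the retinoic acid receptor RARB and the synaptic gene CBLN2. By edgeR 9620 of 16484 tested genes (58.4%) changed, 4798 higher and 4822 lower, and 5979 of them by at least 1.5-fold. With library size only in place of TMM factors the median of all genes was -0.345 on the log2 scale and 2641 genes were higher and 8150 lower, so changes in SNU-475 are relative to that shift. Chromosome medians lay between -0.07 and 0.19. Of the 30 lists 21 had the same counts adjusted over the list alone, and the largest change in a direction was 6 genes, in ribosomal protein genes (0 higher and 9 lower of 35, 0 and 3 adjusted over the list alone, camera adjusted p = 0.0602).

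**Figure D2:**
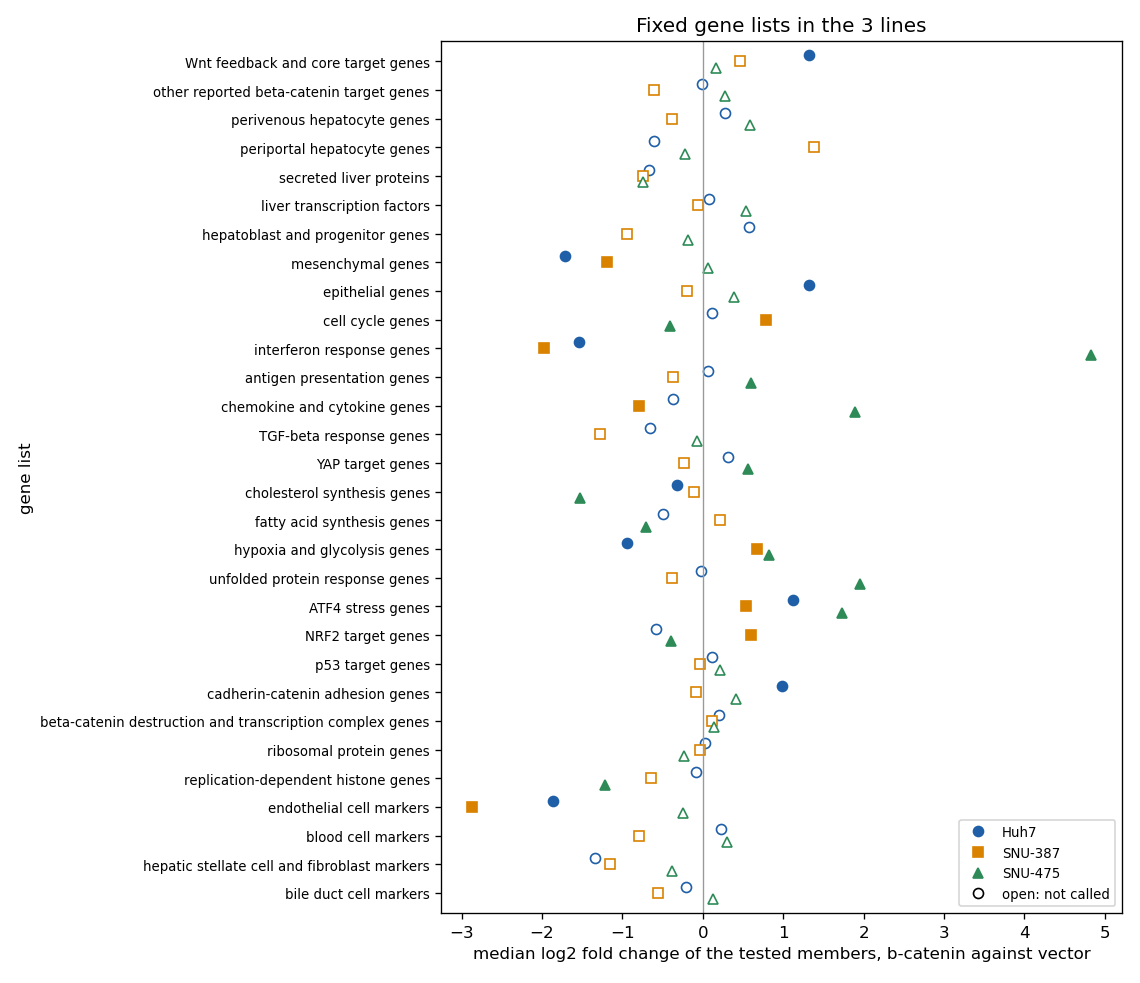
Median log2 fold change, b-catenin against vector, of the tested members of each of the 30 gene lists fixed before the data were examined, with filled symbols for lists called by camera and open symbols for those not called. Interferon response genes have medians of -1.54 in Huh7, -1.98 in SNU-387 and 4.83 in SNU-475, and ATF4 stress genes 1.12, 0.54 and 1.73.

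**Figure D3:**
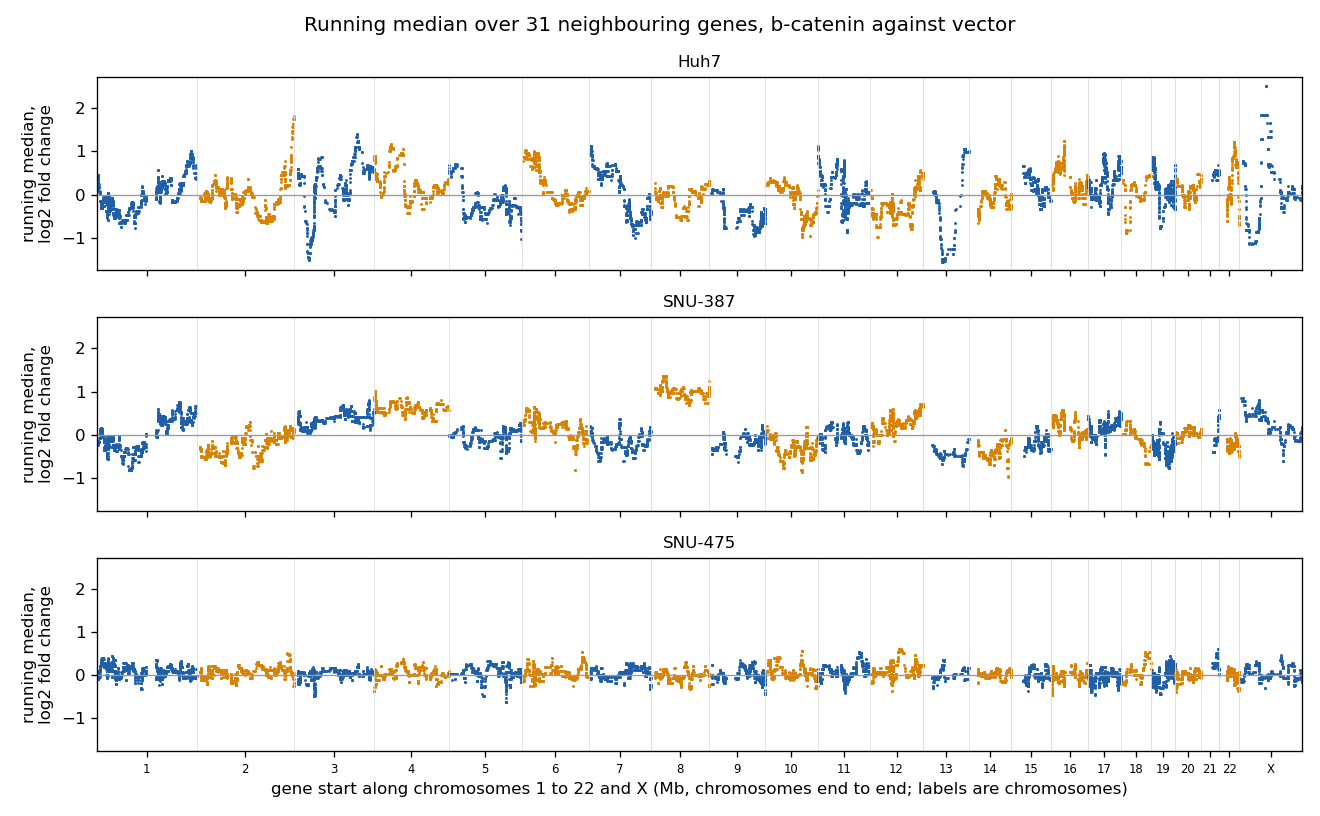
Running median of the log2 fold change, b-catenin against vector, over 31 neighbouring genes in chromosome order for each line. The highest point in Huh7 is 2.52 on chromosome X, chromosome 8 of SNU-387 lies high throughout with a median of 1.01, and no window of SNU-475 lies beyond 0.7.

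The average over the 3 lines weights each line equally, and 1 line can carry it. Amino acid stress genes were higher and sterol genes lower on average. All 23 tested ATF4 stress genes were higher, with a median of 1.06 (camera adjusted p = 6.87e-16), and 20 of 21 cholesterol synthesis genes were lower and 0 higher, with a median of -0.69 (camera adjusted p = 6.97e-08). In SNU-387 by itself the cholesterol list was mixed, with 7 higher and 9 lower of 21 and a median of -0.11 (camera adjusted p = 0.884). Unfolded protein response genes had 12 higher and 1 lower of 19 and a median of 0.53 (camera adjusted p = 0.000184), which SNU-475 carried (1.96), since the medians were -0.03 in Huh7 and -0.385 in SNU-387 (1 higher and 11 lower). Interferon response genes had 19 higher and 4 lower of 34 and a median of 0.35, or 0.41 with scarce genes at their bound (camera adjusted p = 2.49e-05), an average of opposite changes in single lines. Each of these 4 lists held with an estimated correlation (adjusted p = 0.0151 for each). The single genes with the highest averages among those with more than 3 counts in each group were the fucosyltransferase gene FUT1 (4.36, edgeR adjusted p = 3.9e-10), HPD, which breaks down tyrosine (4.12, 1.59e-14), the zinc finger gene ZNF239 (3.79), NKD1 (3.63, 1.42e-10), the X-linked WWC3 (3.35) and the transcription factor FOXQ1 (3.32, 1.59e-14). HPD had 26.8 against 0.574 CPM in Huh7, 30.7 against 0.625 in SNU-387 and 18.9 against 8.18 in SNU-475. S100A9 and the arginine-modifying enzyme gene PADI2 were lowest with -4.30 and -3.87. FAM155B, ZNF518B, ALDH1L1, LBP, SAMD5, MYCN, ENPP5 and SNCAIP, which the fixed rule names too, had 3 counts or fewer in some group, so their fitted values set no bound.

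Of the other lists called on average, epithelial genes had 9 higher and 1 lower of 22 (8 and 1 adjusted over the list alone) and a median of 0.56, or 0.51 with scarce genes at their bound (camera adjusted p = 0.000858; adjusted p = 0.0902 with an estimated correlation). Wnt feedback and core targets had 13 higher and 6 lower of 21 (14 and 7 adjusted over the list alone) and a median of 0.39 (camera adjusted p = 0.021; adjusted p = 0.322 with an estimated correlation). Cell cycle genes had 15 higher and 4 lower of 32 (16 and 4 adjusted over the list alone) and a median of 0.17 (camera adjusted p = 0.00863; adjusted p = 0.233 with an estimated correlation; 0.0712 with library size only, range over 21 alternatives 0.00713 to 0.0712), an average of opposite called changes in SNU-387 and SNU-475. Mesenchymal genes had 16 lower and 4 higher of 26 and a median of -0.88 (camera adjusted p = 0.000209; adjusted p = 0.0902 with an estimated correlation). Stellate cell and fibroblast markers had 11 lower and 1 higher of 19 and a median of -0.45 (camera adjusted p = 0.0112; adjusted p = 0.2 with an estimated correlation). TGF-beta response genes had 13 lower and 3 higher of 20 and a median of -0.34, or -0.37 with scarce genes at their bound (camera adjusted p = 0.00511; adjusted p = 0.322 with an estimated correlation). Histone genes had 8 lower of 16 and a median of -0.48 (camera adjusted p = 0.0213, and 0.322 with an estimated correlation). Of the 17 members 5, 6 and 9 reached 1 CPM in the vector libraries of Huh7, SNU-387 and SNU-475. Endothelial markers had 7 lower of 14 and a median of -1.03, or -1.02 with scarce genes at their bound (camera adjusted p = 0.00559; adjusted p = 0.128 with an estimated correlation; 0.0614 without the Huh7 libraries b-catenin 1 and vector 3, range 0.00407 to 0.0614). Of these lists the epithelial and Wnt lists were called in Huh7 alone, histone genes in SNU-475 alone, mesenchymal genes and endothelial markers in Huh7 and SNU-387, and stellate cell markers and TGF-beta genes in no single line. By edgeR 9160 of 18318 genes changed on average, 4219 higher and 4941 lower, and 4660 of them by at least 1.5-fold. With library size only the median of all genes was -0.166 on the log2 scale, with 2887 genes higher and 5921 lower.

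Genes called in the same direction in each line were more than independent lists would give, but most of their number is expected by chance. The overlap of 3 lines was not tested, so a single gene named here may coincide by chance. CHAC1 rose by 3.95, 2.23 and 2.49 on the log2 scale in Huh7, SNU-387 and SNU-475, MTHFD2 by 1.75, 2.67 and 1.43, and CBS, which feeds cysteine synthesis, by 2.37, 2.22 and 0.88. The hexokinase relative HKDC1, the ubiquitin ligase gene SIAH2, the transaminase gene GPT2, HPD and the coactivator gene ZMIZ2 were higher in each line as well. The receptor gene FZD7 fell by 1.62, 1.83 and 1.70, the cytokine inhibitor SOCS3 by 2.64, 1.16 and 1.64, and the desaturase gene SCD5 by 2.32, 3.75 and 2.05. ADAM23, the histamine-degrading enzyme gene HNMT, TSPAN7 and the antisense transcript HAGLR, counted without stated strand, were lower in each line too. Of 13881 genes tested in each line 394 were called higher in all 3, against 330.4 by chance overlap of independent lists, and 411 lower against 285.5. All libraries labelled b-catenin lay above all vector libraries in each line for 491 of 18318 genes and below for 794, against 357.8 and 591.5 if the lines were independent and 2.29 per direction if nothing changed in any line.

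Pairs of lines shared more genes than chance in each direction, except for higher genes in Huh7 and SNU-475. Huh7 and SNU-387 shared 1299 higher genes of 14286 tested in both, against 1118 by chance (odds ratio 1.37, Fisher's exact p = 3.26e-14, adjusted 9.78e-14), and 1295 lower genes against 1022 (1.65, p = 1.15e-31, adjusted 6.9e-31). SNU-387 and SNU-475 shared 1642 higher genes of 14903 against 1548 (1.14, Fisher's exact p = 0.000438, adjusted 0.000657) and 1772 lower genes against 1594 (1.28, p = 4.14e-11, adjusted 8.28e-11). Huh7 and SNU-475 shared 939 higher genes of 14498 against 948.5 (0.982, Fisher's exact p = 0.693) and 958 lower genes against 885 (1.16, p = 0.00122, adjusted 0.00146). They also had 1948 genes called in opposite directions against 1833 by chance, so the sharing in that pair was not specific to direction. Genes are not independent, so these p-values are lower than replicate libraries would give. Of the genes called in both lines 57.5% of 4515 in Huh7 and SNU-387 had the same sign, 52.7% of 6483 in SNU-387 and SNU-475 and 49.3% of 3845 in Huh7 and SNU-475. The correlation of log2 fold changes across genes was 0.098, 0.039 and -0.015 for these pairs. Together 2594, 3414 and 1897 genes were shared in direction. Without the Huh7 libraries b-catenin 1 and vector 3 the pairs with Huh7 shared 4397 and 3141, a rise that the choice of the farthest libraries favours.

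The interaction test asks whether the change with the b-catenin label differs between lines. Between SNU-475 and Huh7 9002 genes differed, 4511 higher and 4491 lower, led by RSAD2 (difference of log2 change 13.87), CMPK2 (11.86), OAS2 (11.50) and OASL (11.41), which were below 3 CPM in Huh7, and by GYPC (-10.44). Interferon response genes differed by a median of 6.99, or 6.38 with scarce genes at their bound, with 32 of 34 higher and 1 lower. Chemokine genes differed by 2.40 (2.34 with scarce genes at their bound), hypoxia and glycolysis genes by 1.95, unfolded protein response genes by 2.13 and cholesterol synthesis genes by -1.15, each held with an estimated correlation (adjusted p = 7.68e-06, 0.0246, 0.000499, 0.000376 and 0.0209 in that order). Between SNU-475 and SNU-387 8576 genes differed, 4320 higher and 4256 lower, with OASL at 11.89 and LTF at 11.19, and the Wnt antagonist SOST (-8.28), FLG (-8.16), LGR5 (-7.96) and the galectin LGALS12 (-7.75) on the other side. LGR5 had fewer than 0.05 CPM in both SNU-475 groups. LTF had 0.261 against 0.0690 CPM in SNU-475 and 0.0480 against 30.39 CPM in SNU-387, so its value rests mainly on the fall in SNU-387. Interferon response genes differed by 7.23 (7.20 with scarce genes at their bound), chemokine genes by 2.09, unfolded protein response genes by 2.46, mesenchymal genes by 1.41, cholesterol synthesis genes by -1.47, cell cycle genes by -1.31 and NRF2 targets by -1 (adjusted p = 7.39e-06, 0.00593, 0.000207, 0.0431, 0.0107, 0.00373 and 0.0107 with an estimated correlation). Between SNU-387 and Huh7 8762 genes differed, 4400 higher and 4362 lower, with FAM151A (11.09), DUSP2 (10.93) and UBE2QL1 (10.55) highest and the guidance genes SEMA3E (-14.34) and SEMA5A (-12.74) and ZPLD1 (-12.61) lowest. Hypoxia and glycolysis genes differed by 1.53 and NRF2 targets by 1.49 (adjusted p = 0.00239 and 0.00593 with an estimated correlation).

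The named genes of these differences are those of the fixed rule with more than 3 counts in each of the 4 groups. AXIN2, chosen after its values were seen, changed more in SNU-387 than in Huh7 (2.65, edgeR adjusted p = 5.02e-07) or SNU-475 (-4.11, edgeR adjusted p = 3.46e-09), and less in SNU-475 than in Huh7 (-1.47, edgeR adjusted p = 0.000227). With library size only the medians of all genes were -0.227 for SNU-475 minus Huh7 and -0.277 for SNU-475 minus SNU-387, and the shares of called genes that were higher were 38.5% and 36.0% against 50.1% and 50.4%. List counts adjusted over the list alone were the same for 21, 23 and 18 of the 30 lists (SNU-387 minus Huh7, SNU-475 minus Huh7, SNU-475 minus SNU-387), with changes of up to 3, 2 and 3 genes per direction.

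The vector libraries show how the lines differ without the b-catenin label. Secreted liver proteins were far lower in the SNU lines than in Huh7. Of 28 such genes 27 had at least 1 CPM in Huh7, 7 in SNU-387 and 8 in SNU-475, and of 20 liver transcription factors 19, 8 and 14. ALB, serum albumin, had 10110 CPM in Huh7, 0.107 in SNU-387 and 0.0173 in SNU-475, and the fibrinogen gene FGA 1143, 0.729 and 0.723 CPM. APOB, the main protein of LDL, had 3074 CPM in Huh7 and 0 counts in both SNU lines, AHSG and APOA2 had 1 count or none there, and FGB and GPC3 had 1 count in SNU-387. The liver transcription factor gene HNF4A had 149 CPM in Huh7, 1.30 in SNU-387 and 5.73 in SNU-475. SPARC had 29.2, 4530 and 1429 CPM, the receptor kinase AXL 0.251, 353 and 165 CPM, and COL6A2 6.52, 699.6 and 519 CPM. POSTN, PMEPA1, MSC and MGP had 0 counts in Huh7 vector and MMP2 had 1. AKR1B10 had 0.542, 154 and 3161 CPM and DKK1 240.0, 46.6 and 3.83 CPM. AXIN1, a scaffold of the beta-catenin destruction complex, had 29.6 CPM in Huh7, 46.0 in SNU-387 and 0.0165 in SNU-475, which was 3 counts over 3 libraries. AMER1 had 0.150 CPM in Huh7 and 3.78 and 5.17 CPM in the SNU lines. The cytokine genes CXCL8 and IL1B had 438 and 134 CPM in SNU-387 and 2.6 and 0.275 in SNU-475. TWIST1 had 0.359 and 52.97 CPM, and NDN, GAGE7, GAGE12B and GAGE2A, GAGE2C and GAGE2E, the GAGE genes being near copies of uncertain count, were highest in SNU-475. GAGE2A lost its calls with limma-voom (adjusted p = 0.0731 against Huh7 and 0.0789 against SNU-387) and with the replicate number as a block in edgeR (adjusted p = 0.104 and 0.122). Against Huh7 its call was also lost without the Huh7 libraries b-catenin 1 and vector 3 (edgeR adjusted p = 0.0539). TCN1, KLRC2, SLITRK6, ODAM and SLCO1B3 had at most 1 count in SNU-475 and between 9.73 and 63.9 CPM in SNU-387.

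Lists separated the vector libraries in the same way. Secreted liver proteins had 26 of 27 lower in SNU-387 than in Huh7, with a median of -10.61 (-10.56 with scarce genes at their bound), and 27 of 27 lower in SNU-475, with -10.64 (-9.67 at the bound), adjusted p = 0.00144 and 0.000828 with an estimated correlation. Liver transcription factors (-6.11 and -5.07, adjusted p = 0.0106 and 0.00986 with an estimated correlation) and hepatoblast genes (-5.32 and -2.25, adjusted p = 0.00969 and 0.0157) were lower in both, and mesenchymal genes higher (4.13 and 5.16, adjusted p = 0.00799 and 0.0106). Epithelial genes were lower in SNU-387 than in Huh7 (-2.90, or -2.32 with scarce genes at their bound, adjusted p = 0.0265 with an estimated correlation), and antigen presentation genes were higher there, 16 of 17 with a median of 2.91 (adjusted p = 0.0355). NRF2 targets were higher in both SNU lines than in Huh7 (1.2 and 2.24, adjusted p = 0.0416 and 0.00632 with an estimated correlation) and higher in SNU-475 than in SNU-387 (1.43, adjusted p = 0.00967). SNU-475 had lower chemokine genes than SNU-387 (-3.66, 21 of 24, adjusted p = 0.00662 with an estimated correlation), lower interferon response genes (-1.48, or -1.32 with scarce genes at their bound, adjusted p = 0.0106) and higher cell cycle genes (0.74, adjusted p = 0.0491). By edgeR 12703 genes differed between SNU-387 and Huh7 vector (6335 higher and 6368 lower), 12639 between SNU-475 and Huh7 (6540 and 6099) and 11545 between SNU-475 and SNU-387 (6220 and 5325). With library size only the medians of all genes for SNU-475 were 0.239 against Huh7 and 0.318 against SNU-387, where 66.0% in place of 53.9% of the called genes were higher. List counts adjusted over the list alone were the same for 26, 24 and 24 of the 30 lists, with changes of up to 2, 1 and 1 genes per direction.

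The other 11 fixed lists were called neither in a line nor on average. Other reported beta-catenin target genes had 7 higher and 7 lower of 26 in Huh7, 11 and 15 of 29 in SNU-387 and 14 and 9 of 30 in SNU-475 (camera adjusted p = 0.989, 0.407 and 0.178). Perivenous hepatocyte genes, which Wnt signalling maintains in liver, had 4 and 7 of 15, 5 and 6 of 11, and 5 and 2 of 10, and periportal hepatocyte genes 6 and 4 of 15, 7 and 2 of 12, and 1 and 3 of 11. Secreted liver proteins had 2 higher and 11 lower of 27, 2 and 6 of 10, and 4 and 6 of 13 (camera adjusted p = 0.0562, 0.165 and 0.407). In Huh7 they were called with adjusted p-values of 0.0349, 0.0296 and 0.0336 without b-catenin replicate 1, vector replicate 1 or vector replicate 2 (range over 9 alternatives 0.0296 to 0.125). Liver transcription factors had 4 and 3 of 19, 6 and 5 of 14, and 8 and 4 of 16. Hepatoblast and progenitor genes had 6 and 4 of 16, 6 and 8 of 14, and 4 and 6 of 17, and p53 targets 7 and 6 of 22, 6 and 10 of 23, and 11 and 9 of 23. Genes of the beta-catenin destruction and transcription complexes had 9 and 5 of 32, 15 and 11 of 32, and 11 and 7 of 31. Ribosomal protein genes had 0 and 3 of 35 in Huh7 and 9 and 14 of 35 in SNU-387. In SNU-475 their adjusted p was 0.000764 without b-catenin replicate 2 and 0.0224 without vector replicate 2 (range over 8 alternatives 0.000764 to 0.372). Blood cell markers had 2 and 2 of 6, 2 and 4 of 6, and 4 and 2 of 8, and bile duct markers 6 and 5 of 14, 4 and 5 of 11, and 4 and 3 of 10. The median, mean and test of a list differed in sign for 7 lists in Huh7, 4 in SNU-387, 2 in SNU-475 and 6 on average, of which 0 were called. These were other beta-catenin targets, antigen presentation, histone, blood cell and bile duct genes in Huh7, perivenous and ribosomal protein genes in Huh7 and SNU-387, hepatoblast and epithelial genes in SNU-387, and secreted liver and TGF-beta genes in SNU-475. On average they were other beta-catenin targets and perivenous, periportal, liver transcription factor, antigen presentation and p53 target genes. Of the medians of called lists 0 changed sign with another scaling. In SNU-475 the medians of other beta-catenin targets, mesenchymal, p53 target, destruction complex, blood cell and bile duct genes, between 0.07 and 0.30, were below 0 with library size only.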

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

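Of the tests below, only those of GC content and transcript length were written before their result was seen; the tests of copy number, exchanged lines, blood cells, scaling, a general effect of the label, length bias in single libraries, ribosomal RNA, depth and other splits were chosen after. Groups had 3 libraries, so no outlier test was applied to single libraries.

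The change with the b-catenin label differed between lines by the interaction test for 8762 genes between SNU-387 and Huh7, 9002 between SNU-475 and Huh7 and 8576 between SNU-475 and SNU-387. Of 100 splits of the libraries within their lines, the real one and others drawn at random, 1, the real one, gave as many genes in each case. The highest other splits gave 4357, 5580 and 5617, so labels without effect in any line would seldom give such counts. These splits do not ask whether the changes are equal between lines, so they cannot exclude chance for a difference between lines. For the average over the lines 1 of the 100 splits, the real one, gave 9160, and the highest other 3951. Within single lines and between vector libraries 10 splits are possible, too few for a share under 0.05. There the highest other split called 0 genes with edgeR, against 6875 in Huh7, 11285 in SNU-387, 9620 in SNU-475, and 12703, 12639 and 11545 between vector libraries, and the most genes at an unadjusted p under 0.05 in another split were 726, 151, 525, 1896, 1605 and 161, against 8110, 11598, 10364, 13124, 13066 and 12143 in the real one. In each of these 6 comparisons 1 of the 10 splits, the real one, was as large.

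Lists whose change differed between lines, also with an estimated correlation, were hypoxia and glycolysis genes (median difference 1.53) and NRF2 targets (1.49) for SNU-387 minus Huh7. For SNU-475 minus Huh7 they were interferon response (6.99), chemokine and cytokine (2.40), cholesterol synthesis (-1.15), hypoxia and glycolysis (1.95) and unfolded protein response genes (2.13). For SNU-475 minus SNU-387 they were mesenchymal (1.41), cell cycle (-1.31), interferon response (7.23), chemokine and cytokine (2.09), cholesterol synthesis (-1.47) and unfolded protein response genes (2.46) and NRF2 targets (-1). Single genes by edgeR's interaction test, as differences of log2 change, were FAM151A (11.09), DUSP2 (10.93), UBE2QL1 (10.55), SEMA3E (-14.34), SEMA5A (-12.74) and ZPLD1 (-12.61) for SNU-387 minus Huh7. RSAD2 (13.87), CMPK2 (11.86), OAS2 (11.50), OASL (11.41) and GYPC (-10.44) differed for SNU-475 minus Huh7, and OASL (11.89), LTF (11.19), SOST (-8.28), FLG (-8.16), LGR5 (-7.96) and LGALS12 (-7.75) for SNU-475 minus SNU-387.

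Neighbouring genes changed together in Huh7 and SNU-387: 1687 of 11771 windows of 31 genes in Huh7 and 687 of 11501 in SNU-387 had a median beyond 0.7, against at most 33 and 15 in 200 shuffled gene orders, and 0 of 12091 in SNU-475 against at most 1. Against bias from GC content and length, 1552 and 857 windows were beyond 0.7 after these trends were removed, against at most 37 and 15 in shuffled orders, and against libraries of different lines having been exchanged, the lowest correlation between the groups of a line, 0.931, was above the highest between lines, 0.839. A candidate explanation is that chromosome copy number differs between the labelled groups, as among sublines or clones of 1 line. In Huh7 56 genes, 18 of them on the X chromosome, had over 5 CPM with the label and under 0.3 CPM in vector, and 7 the reverse. The source of the peak of 2.52 at ZC4H2 on the X chromosome was not tested. Whether the label's effect on single genes in these lines can be separated from such a difference between cells stays open, because each group would carry its own.

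Interferon and stress genes were higher in the SNU-475 libraries labelled b-catenin, with list medians of 4.83 and 1.96 (interferon and unfolded protein response). Against scaling, the medians were 4.50 and 1.63 with library size only. Against a general effect of the label on interferon genes, their medians were -1.54 in Huh7 and -1.98 in SNU-387. That test covered interferon genes only. The unfolded protein response medians were below 0 in those lines, but ATF4 stress genes were called higher in each line. Heat shock genes, listed after values were seen, had 10 higher and 2 lower of 13 in SNU-387 and 3 and 3 in Huh7. A general effect on these stress genes was thus not excluded. Against blood cells, PTPRC, LYZ, CORO1A, LAPTM5 and TYROBP together had 3.99 CPM against 3.91 in vector. HBA2, at 39.75 against 0.391 CPM, rose while HBB had 0.0326 against 0 CPM. A response of SNU-475 to the label, to the way the construct was delivered (which the labels do not give) or to an infection or stress of these cultures alone may each give these values. No test here separates these, since all 3 libraries of the group share them.

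Huh7 b-catenin replicate 1 and Huh7 vector replicate 3 stood apart from their groups: their deviations had SDs of 0.923 and 0.644 on the log2 scale, and the next highest library of the series had 0.590. Ribosomal RNA may be a source for the first, which had 21.97% against 5.38% and 1.996% in its group, but not for the second, which had 4.54%, the lowest of its group (next 6.57%). Against depth alone the first had the highest total count of its group, 54236902, and the second, with 44488356, the lowest. Longer transcripts were lower in both (Spearman correlation of the deviation with transcript length -0.445 and -0.605 across genes), which may be bias from RNA quality or library preparation. Their deviations correlated at 0.525 with each other, the highest of 27 pairs of a b-catenin and a vector library of 1 line, so a source shared by both is possible. Length bias cannot be told apart from ordinary variation between libraries, because SNU-475 b-catenin replicate 2 had -0.523 with a deviation of 0.498. No biological explanation was tested, since the labels give none within a group.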

How the results depend on the processing

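Leaving out Huh7 b-catenin replicate 1 and vector replicate 3 together and removing the ribosomal RNA genes were chosen after the results were seen; the other alternatives were planned. Unless a cause is given, the cause was not tested.

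Of the counts of changed genes, those named next moved by more than 1.5 times and the others did not. Without the 2 Huh7 libraries 11683 genes were called in Huh7 in place of 6875, 4397 were shared by Huh7 and SNU-387 in place of 2594 and 3141 by Huh7 and SNU-475 in place of 1897. Of the 6875 calls 6861 kept their direction without these libraries. They were chosen as the farthest from their groups, so the spread within groups falls and the rise in calls is in part built in. With a fold change of at least 1.5 the counts were 7219 in SNU-387, 5979 in SNU-475, 4660 on average, and 1641, 1118 and 1430 for the overlaps (Huh7 and SNU-387, Huh7 and SNU-475, SNU-387 and SNU-475), which follows from the stricter threshold.

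With the replicate number as a block 7644 genes differed between SNU-475 and SNU-387 vector in place of 11545, and Huh7 and SNU-475 shared 1201 in place of 1897. No other count moved by more than 1.5 times. The block ended 1 of 41 list calls (NRF2 targets in SNU-475, adjusted p = 0.0547) and the calls of GAGE2A between vector libraries (adjusted p = 0.104 against Huh7 and 0.122 against SNU-387), and no other named call. No pairing by number was detected: of the 6 libraries of a line, 1 in Huh7, 2 in SNU-387 and 0 in SNU-475 correlated best with the library of its own number. The 2 in SNU-387 are 1 pair, replicate 3 of each group (correlation 0.075). With 3 libraries per group this check cannot exclude pairing.

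Leaving out 1 library at a time gave 4692 to 8211 genes in Huh7, 10693 to 11343 in SNU-387, 7797 to 11031 in SNU-475 and 8592 to 10284 on average. The differences were 8103 to 9662 (SNU-387 minus Huh7), 8205 to 9637 (SNU-475 minus Huh7) and 7737 to 9986 (SNU-475 minus SNU-387), the vector comparisons 11977 to 13722, 11834 to 13743 and 10622 to 12789, and the overlaps 1761 to 3079, 1339 to 2313 and 2801 to 3818. CTNNB1 changed by -0.27 to 0.26 in Huh7, 0.50 to 0.64 in SNU-387 and 0.13 to 0.29 in SNU-475. In SNU-475 it was called without b-catenin replicate 2 (0.29, edgeR adjusted p = 0.00394) and in no other alternative. Over the alternatives with every library kept it changed by -0.13 to 0.22 in SNU-475, so its sign there depends on the processing. Without Huh7 b-catenin replicate 1 the average of CTNNB1 was called too (0.32, adjusted p = 0.000806, range over 27 alternatives 0.000342 to 0.539).

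Of the 41 list calls, 6 held with an estimated correlation, and fry, which tests each list alone, called 91, among them all 41. Leaving out single libraries gave 40 to 46 calls. With library size only 39 of the 41 were kept and 3 gained (secreted liver proteins in Huh7, liver transcription factors and ribosomal protein genes in SNU-475, adjusted p = 0.0391, 0.0371 and 0.0383). Calls gained without 1 library were NRF2 targets (without vector replicate 2), destruction complex and ribosomal protein genes (without b-catenin replicate 1) in Huh7, with adjusted p-values of 0.0391, 0.0494 and 0.0434 (ranges to 0.118, 0.471 and 0.912), periportal genes in SNU-387 (0.0439, 0.0356 and 0.0450 without b-catenin replicate 1, vector replicate 2 or vector replicate 3, range to 0.0701) and antigen presentation genes in SNU-387 (0.0366 without vector replicate 2, range to 0.104). On average, destruction complex genes were called in 5 of 21 alternatives (0.0238 to 0.11), 0.0238 without Huh7 b-catenin replicate 1, and ribosomal protein genes in 1 (0.0382 without the same library, range to 0.802).

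Over 315 pairs of a named gene and a comparison, 6040 alternatives gave the same call, 5 lost the call, all for GAGE2A, and 7 gained one. Of the changes called in the main or the alternative setting 0 reversed. A change of sign between values that were both not called was counted as the same call. Besides those given, GAGE2A lost its call with limma-voom (adjusted p = 0.0731 and 0.0789) and, against Huh7, without the 2 Huh7 libraries (0.0539). The calls gained were those of CTNNB1 on average and in differences and of AXIN2 in SNU-475 (-0.34 with library size only); the changes of CTNNB1 in single lines are counted apart, and the call gained in SNU-475 is given above. That setting gave a median of all genes in SNU-475 of -0.345 in place of -0.016 and moved its share of higher genes among those called from 49.9% to 24.5%, on average from 46.1% to 32.8%. For 564 of the 9620 genes called in SNU-475 the sign changed.

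Depth limits what can be said of genes with few counts: genes with 3 counts or fewer in a group have bounds or wide intervals. In simulated counts with few genes changed, 1.49% of 1.5-fold changes were recovered in Huh7 and 62.7% in SNU-387 at similar totals. The biological coefficient of variation was 27.3% in Huh7 and 9.44% in SNU-387. Depth was not varied in the simulation, so it cannot rank spread between replicates against depth. The share recovered need not hold for the real Huh7 data, where 43.9% of the genes were called. Of these 6875 calls 6376 were of at least 1.5-fold and 4483 of at least 2-fold.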

Other observations

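The genes and lists below were chosen after their values were seen, and no explanation was tested for them.

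Huh7 libraries labelled b-catenin carried less RNA of several liver genes than vector libraries. Fibrinogen beta (FGB) had 212 ± 29.2 against 1572 ± 136 CPM, plasminogen (PLG) 0.312 ± 0.193 against 15.5 ± 0.616 CPM, antithrombin (SERPINC1) 0.373 ± 0.207 against 16.6 ± 2.82 CPM, and the bile acid receptor gene NR1H4 8.73 ± 1.84 against 110.5 ± 5.00 CPM (edgeR adjusted p = 6.19e-05, 0.000144, 0.000156 and 4.3e-05). The Wnt-inactivating enzyme gene NOTUM had 37.2 ± 1.29 against 10.1 ± 2.02 CPM, and CD74, the chaperone of class II molecules, 37.1 ± 0.614 against 0.931 ± 0.212 CPM. The neural adhesion gene L1CAM rose in Huh7 from 1.52 ± 0.203 to 29.1 ± 11.3 CPM and fell in SNU-387 from 118.8 ± 7.89 to 5.44 ± 0.199 CPM. In SNU-387 the TGF-beta feedback gene PMEPA1 fell from 332 ± 13.6 to 27.95 ± 0.784 CPM and SOX9 from 106 ± 1.52 to 33.8 ± 2.54 CPM.

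In SNU-475 the heat shock genes HSPA1A and HSPA1B, near-identical copies whose counts are uncertain one by one, had 17850 ± 247 and 7266 ± 827 CPM against 495 ± 15.2 and 303 ± 6.96 CPM, and their partner DNAJB1 2249 ± 13.3 against 206.8 ± 5.12 CPM. Of 13 heat shock genes 13 were higher in SNU-475 (median log2 fold change 2.73), 10 were higher and 2 lower in SNU-387 (1.02), and 3 and 3 in Huh7 (0.19). Complement C3 rose from 73.1 ± 3.76 to 365 ± 27.5 CPM in SNU-475, and the matrix gene DCN fell from 19.1 ± 0.269 to 2.29 ± 0.613 CPM. The ubiquitin-like ISG15 had 1345 ± 201 against 27.97 ± 3.16 CPM. Of 16 cancer-testis genes 4 of 13 tested were higher and 1 lower in SNU-475, 2 higher and 4 lower of 6 in SNU-387, and 0 and 2 of 3 in Huh7. Between vector libraries of the lines, 604 genes (SNU-387 and Huh7), 687 (SNU-475 and Huh7) and 351 (SNU-475 and SNU-387) were under 0.3 CPM in 1 line and over 5 CPM in the other.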
